A study of Mus musculus with 15 samples.

How the data were processed

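Gene expression was measured on 15 Affymetrix mouse arrays, 1 per sample, hybridised with RNA of TER119-positive cells from E13.5 fetal liver. TER119 is a surface antigen of maturing erythroid cells, and per the labels' protocols the cells were purified with magnetic beads against it. RNA was extracted with TRI-Reagent, cleaned on columns and labelled with biotin, also per the labels. The deposited values are log2 signals, 1 per transcript cluster and array. The tools RMA and Partek are named in the submitters' processing notes, with no version given. The platform's genome build is not given in the sources used here, so no coordinates are reported. The array medians lay between 6.28 and 6.41 and single values between 2.09 and 14.89. The values carry no detection call, so no fold is given where the mean of a group compared lies below the array medians, and no size at all for a named gene where it lies under the lower quartile of each array of that group. Correlations between arrays ranged from 0.974 to 0.992, and no 2 arrays held identical values. All 15 columns of the table belonged to samples of the study.

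Of 35556 transcript clusters, 21789 had 1 gene symbol in the platform annotation of 2016, 1621 had several and 12146 had none. Gene identifiers of 21698 clusters matched the gene table of assembly GRCm38.p6, which changed 0 symbols. The tests ran over the 23410 clusters with at least 1 symbol. Those clusters with 1 symbol stood for 19938 genes. No gene is named from a cluster with several symbols, and clusters without a symbol are only counted. Where a gene had more than 1 cluster, the one with the highest mean signal stood for it in a gene list. Counts of calls are counts of clusters.

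The labels give 4 genotypes on the FVB/NJ background, with 4 wild-type, 4 Klf8 gene-trap, 3 Klf3-null and 4 doubly mutant arrays. Samples are stated to be litter-matched where this could be done, but the labels do not say which arrays share a litter, or that each array is a separate embryo. The p-values therefore measure the spread between these samples, which may be partly technical. Over the tested clusters as a whole, replicate numbers pair arrays in 1 comparison only, by the data and not by the labels. Between doubly mutant and Klf8-trap arrays, the deviations from the group means of all 4 same-numbered pairs correlated above 0.1 (0.114 to 0.534), and of 24 ways to match these arrays none other had a mean as high (0.247). The number of arrays limits the precision, with a median standard error of 0.11 on the log2 scale for groups of 4 and 0.12 for a comparison with the group of 3.

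The log2 values were used as deposited. A linear model with 1 mean per genotype was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3, followed by eBayes without a trend. The prior had 4.27 degrees of freedom. Contrasts were each mutant group against wild type, the doubly mutant arrays against each single mutant, and the interaction of both genotypes. All tests were two-sided. P-values were adjusted by the method of Benjamini and Hochberg over the 23410 clusters of each contrast, with a threshold of 0.05. Intervals are 95% intervals. Every adjusted p in the text is from this limma fit unless another test is named. Single values of Klf3, Klf8 and the embryonic globins were also compared by exact two-sided permutation of the arrays of both groups.

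Gene lists were fixed before the data were examined. They covered embryonic and adult globins, the Kruppel-like factor family, KLF3 corepressors and partners, published KLF3 targets, KLF1-activated erythroid genes, erythroid transcription factors, haem synthesis and iron, red cell membrane and skeleton, late erythroid maturation, cell cycle, apoptosis and p53 targets, interferon response, stress response, primitive erythroid aquaporins, Y-linked and X-inactivation genes, and genes next to Klf3. Further lists held markers of hepatocytes, macrophages, megakaryocytes, granulocytes and myeloid cells, haematopoietic progenitors, endothelium, mesenchymal and stellate cells, and lymphoid and mast cells. Of 323 listed genes, 294 had a cluster of their own. The adult globins had 0, because their clusters name several genes, and 24 lists were tested. Lists were tested with camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, each adjusted over the 24 lists of a contrast.

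Genes were named by a rule that was also fixed beforehand. It took Klf3, Klf8 and the globins, every list member past the threshold, and in each direction the 10 genes with the largest change among those past the threshold whose arrays did not overlap between groups. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were named as not past the threshold. Predicted genes and Riken clones were skipped. A few further genes from the fit without a Klf8 gene-trap array are named where that fit is described, and were chosen after their values were seen.

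The procedure was tested on simulated data in which 50 of 23410 genes were changed at each of 4 sizes. For the contrast of doubly mutant and wild-type arrays it recovered 40% of the genes changed by 0.5 on the log2 scale, 90% of those changed by 1 and 98% of those changed by 1.5, and 1.80% of its calls were false. For Klf3-null against wild-type arrays 7.57% of the calls were false. The simulated noise was independent between genes and between arrays. These rates therefore do not cover arrays that shift in many genes together, as some of the real arrays did.

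Alternatives fixed beforehand were the replicate number as a block, the mean of 3 Y-linked genes as a covariate, leaving out dim clusters, testing all clusters of the table, eBayes with a trend and robust fit, an unmoderated linear model, fitting only the groups compared, quantile normalization, median centring, array weights, a 1.5-fold minimum, a threshold of 0.1, and leaving out each array. Chosen after seeing the data were the mean hepatocyte signal as a covariate, the mean macrophage signal as a covariate, male embryos alone, the macrophage signal with each doubly mutant array left out, the hepatocyte signal without doubly mutant replicate 1 or Klf8-trap replicate 1, leaving out both arrays that stood apart from their groups, the replicate number as a block of doubly mutant and Klf8-trap arrays alone, and comparing the effect of 1 allele between separate arrays. Simulations and random regroupings used 100 draws with seed 1, and correlations across arrays 100000 permutations.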

Results

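Transcript levels were compared in TER119-positive cells of E13.5 mouse fetal liver, which are mostly erythroid cells at the stage of definitive erythropoiesis. KLF3 is a zinc finger repressor that binds CACCC-type motifs and recruits the corepressor CtBP, and KLF8 is a closely related repressor encoded on the X chromosome. The arrays comprised 4 wild-type samples, 4 samples carrying a gene trap in Klf8, 3 Klf3-null samples and 4 samples carrying both alleles, called doubly mutant here. The design asks what loss of each factor changes alone and whether loss of both changes more. By the level of the Y-linked genes and Xist, 9 arrays came from male and 6 from female embryos. All 4 wild-type arrays were male, whereas the Klf8-trap and doubly mutant groups each held 2 males and 2 females, and the Klf3-null group held 1 male and 2 females.

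The targeted genes were examined first. The Klf3 signal did not fall in the arrays labelled Klf3-null. It was 11.32 ± 0.14 (SD, n = 3) there and 11.37 ± 0.28 (n = 4) in doubly mutant arrays, against 10.27 ± 0.17 in wild-type and 10.27 ± 0.04 in Klf8-trap arrays (n = 4 each). In limma the Klf3 signal was thus higher by 1.04 ± 0.13 (SE) on the log2 scale in the arrays labelled Klf3-null than in wild-type arrays (adjusted p = 6.37e-04). A transcript cluster can rest on probes outside a deleted segment, so this signal does not check the Klf3 label. The labels rest on the submitters' genotyping wherever a Klf3 effect is given here. With 3 arrays against 4, an exact permutation test cannot go below p = 0.0571, and it gave that value. Among male embryos alone, 1 array labelled Klf3-null remained and the Klf3 call was lost (adjusted p = 0.125; 27 of 28 alternatives kept it, with adjusted p from 3e-06).

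Klf8 lay below the array medians of 6.28 to 6.41 in wild-type (5.36 ± 0.18) and Klf8-trap arrays (5.39 ± 0.09), with a difference of 0.02 ± 0.20, so that the trap could not be checked on a Klf3-intact background. In the arrays labelled Klf3-null, Klf8 was higher than in wild type by 3.35 ± 0.22 on the log2 scale (adjusted p = 8.78e-07), at 8.71 ± 0.26. In doubly mutant arrays it reached 7.29 ± 0.55, which was 1.93 ± 0.20 above wild type (adjusted p = 4.76e-05) and 1.42 ± 0.22 below the arrays labelled Klf3-null (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0265). The last difference was past the threshold in 19 of 27 alternatives, with adjusted p from 1.56e-04 to 0.473, and it missed the threshold without doubly mutant replicate 3 (adjusted p = 0.0872) and without Klf3-null replicates 1, 2 and 3 (0.19, 0.25 and 0.0655).

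**Figure D1:**
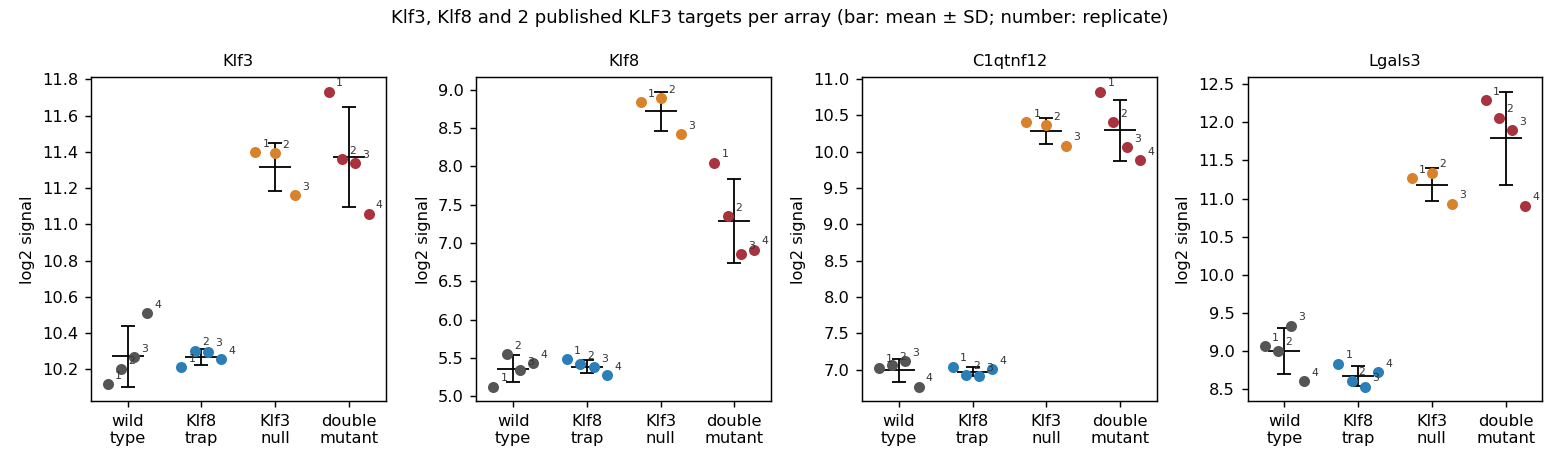
Log2 signal of Klf3, Klf8, C1qtnf12 and Lgals3 on each of the 15 arrays, by the genotype on the label; points are arrays numbered by replicate, and bars give the mean ± SD. All 4 genes lay higher in the Klf3-null and doubly mutant groups, and Klf8 averaged 8.71 in the former and 7.29 in the latter.

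Arrays labelled Klf3-null differed from wild type mainly by genes that were higher. The largest rise was in Pqlc3, a PQ-loop membrane protein, which rose 16.5-fold (4.04 ± 0.22 on the log2 scale). Rragd, a Rag GTPase that relays amino acid levels to mTORC1, rose 14.6-fold (3.87 ± 0.37). C1qtnf12, which encodes the secreted protein adipolin, rose 9.81-fold (3.29 ± 0.17), and Lgals3, encoding the lectin galectin-3, rose 4.52-fold (2.18 ± 0.25). Spi1, which encodes PU.1, a transcription factor of the myeloid lineage, rose 3.22-fold (1.69 ± 0.20; adjusted p = 0.0612 among male embryos alone). The remaining genes among the 10 largest rises were Supt3, a subunit of the SAGA complex, Kdelr3, a receptor that retains proteins in the endoplasmic reticulum, Prune2, Arl15, S100a10 and Dffb, with log2 differences between 2.55 and 2.27. The second transcript cluster of Prune2 did not move with the first (-0.18 against 2.38).

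Fewer genes were lower. Grap2, a lymphoid signalling adaptor, fell 2.24-fold (-1.16 ± 0.21) and Septin1 fell 2.01-fold. The guanylate-binding protein gene Gbp2b (-1.08) fell as well, with a signal below the array medians in arrays labelled Klf3-null. Lipo3 fell to a mean under the lower quartile of each of these arrays, so the size of its fall is not given. Pik3r1, the regulatory subunit of phosphoinositide 3-kinase, fell 1.97-fold (-0.98 ± 0.16). The cochaperone Dnaja4, Pdzk1ip1, Asb2, the T cell costimulator Icos and Tmem26 completed the 10 largest falls, with log2 differences from -0.89 to -0.64. The call of Tmem26 was lost on leaving out any of 11 of 15 arrays, Septin1 of 10, Dnaja4 of 6, Grap2 of 5, Icos of 4 and Asb2 of 1. Their adjusted p without Klf3-null replicate 3 was 0.244, 0.26, 0.141, 0.0851, 0.12 and 0.0546. Tmem26 (adjusted p = 0.0564) and Septin1 (0.0753) also missed the threshold with the macrophage signal as a covariate, and Pdzk1ip1 (0.118) and Lipo3 (0.149) among male embryos alone. In all, 137 of 23410 transcript clusters passed the threshold in limma, 122 higher and 15 lower, and at each of the 137 the arrays of both groups did not overlap. The count fell to 61 without Klf3-null replicate 1, and to 40 among male embryos. It was 296 without both arrays that stood apart from their groups (doubly mutant replicate 1 and Klf8-trap replicate 1), an alternative chosen after seeing the data.

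Among the lists, 3 of 3 published KLF3 targets rose (Lgals3, C1qtnf12 and Klf8), and the same 3 rose when adjusted over the list alone. Their median difference was 3.29, and camera called the list with the preset correlation (adjusted p = 1.05e-18) and with an estimated correlation (adjusted p = 0.00265). These targets were reported from Klf3-null mouse cells and tissues, and so are not independent evidence of direction. Of 17 measured members of the Kruppel-like factor family only Klf3 and Klf8 passed, also when adjusted over the list alone. Of the progenitor markers, 1 of 12 (Spi1) passed. The aquaporin genes Aqp3 and Aqp8, which mark primitive erythroid cells, had a median difference of 0.55; 0 of 2 passed over all genes and 2 of 2 were higher when adjusted over the list alone. Camera called that list (adjusted p = 0.00698, and 0.135 with an estimated correlation). Within groups it went down where embryonic globins went up (r = -0.843), so its rise does not show more primitive erythroid cells. The macrophage list was lower by a median of 0.33 (-0.33), with 0 of 15 members past the threshold over all genes and 1, Cd5l, adjusted over the list alone (camera adjusted p = 0.00494; adjusted p = 0.699 with an estimated correlation). The call was lost without Klf3-null replicate 3 (median -0.20, adjusted p = 0.233) and without wild-type replicate 3 (-0.26, 0.0534). The test fry asks whether the genes of a list change together without regard to other genes, and it called the published targets, the aquaporins (adjusted p = 0.031) and the Kruppel-like factor family (adjusted p = 0.0425). No erythroid list was called.

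Doubly mutant arrays differed from wild type at 772 transcript clusters, 356 higher and 416 lower. The largest rises were again in Rragd (22.6-fold, 4.50 ± 0.35), Pqlc3 (16.1-fold, 4.01 ± 0.21), Kdelr3 (3.46 ± 0.17), C1qtnf12 (9.88-fold) and Supt3 (9.05-fold). Lgals3 rose 6.90-fold and Spi1 4.54-fold, and Cttnbp2nl, Prune2, S100a10 and the cytochrome P450 gene Cyp4f39 rose by 2.56, 2.55, 2.51 and 2.45 on the log2 scale. Cd5l, a secreted protein of tissue macrophages, had the largest fall (5.82-fold, -2.54 ± 0.33), and Grap2 (adjusted p = 1.85e-05), Septin1 (3.58-fold), the prokineticin receptor Prokr1 (3.45-fold) and Pik3r1 (3.03-fold) fell too. The C-type lectin gene Cd209f also fell past the threshold, to a mean of 4.37, under the lower quartile of each doubly mutant array, so the size of its fall is not given. Btnl10 (-1.56), the scavenger receptor gene Marco (-1.54), Plaat3 (-1.53) and the ectonucleotidase gene Entpd1 (-1.51) also fell. With the macrophage signal as a covariate, chosen after seeing the data, Entpd1 gave -0.21 (adjusted p = 0.423), and Plaat3 (-1.71, 0.069), Btnl10 (-1.56, 0.0627) and Cd209f (0.0714) missed the threshold too.

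**Figure D2:**
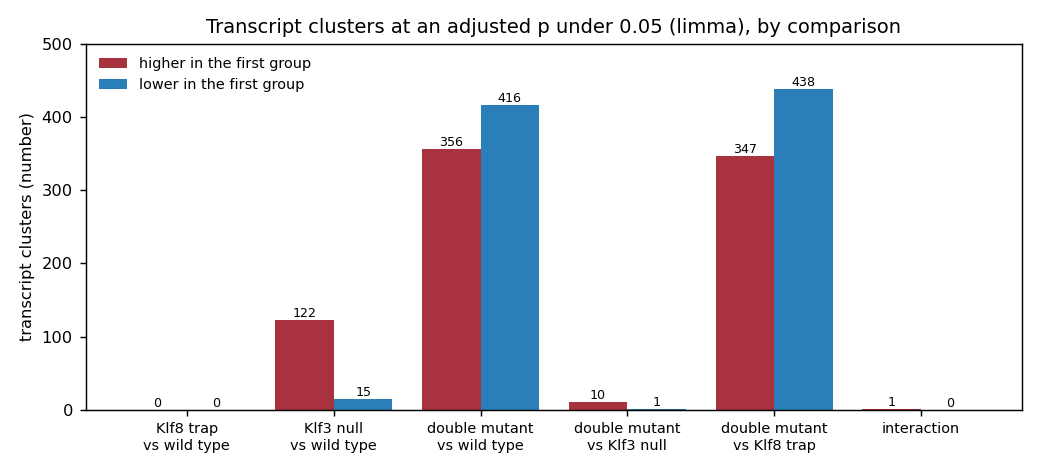
Number of transcript clusters past the threshold in limma, by comparison and direction, out of 23410 tested; the interaction is the difference between the effects of Klf3 loss with and without the Klf8 trap. Counts range from 0 for the Klf8 trap against wild type to 785 for doubly mutant against Klf8-trap arrays.

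Erythroid genes were lower on average in doubly mutant arrays, with few members past the threshold. Klf1, the main erythroid activator of the family, fell by 0.41 on the log2 scale (-0.41 ± 0.11, adjusted p = 0.0487) and Nfe2 by 0.61, whereas Ldb1, a cofactor of GATA1 and TAL1, rose by 0.51 ± 0.07. Adjusted over the list alone, 9 of 19 erythroid transcription factors were lower and 1 higher. In the maturation list, Trim58, a ubiquitin ligase of late erythroblasts, fell 1.97-fold and Ypel4 2.42-fold; 2 of 14 members passed over all genes and 8 when adjusted over the list alone. Of the haem and iron genes, Uros fell by 0.47 and the iron exporter Slc40a1 by 0.85, 2 of 20 over all genes and 6 adjusted over the list alone. With the macrophage signal as a covariate, chosen after seeing the data, the Slc40a1 difference was -0.09 (adjusted p = 0.742; from 6.47e-05 over 28 alternatives, 22 past the threshold). Klf1 (-0.52, adjusted p = 0.122), Uros (-0.62, 0.102), Aqp1 (-0.75, 0.0692) and Ldb1 (0.47, 0.0524) missed the threshold under it as well. The water channel Aqp1 was the only member past the threshold in the red cell membrane list (1 of 21; 3 adjusted over the list alone) and among KLF1-activated genes (1 of 15; 3 adjusted over the list alone), with a fall of 0.84. Camera called all 5 of these lists as lower, with adjusted p from 2.12e-04 to 0.00969, and none with an estimated correlation (adjusted p = 0.501 for each). Without doubly mutant replicate 4 the membrane list lost its call (median -0.15 in place of -0.26, adjusted p = 0.0538) and the maturation median went from -0.41 to -0.27. Without doubly mutant replicate 3 the medians went from -0.24 to -0.11 for transcription factors, from -0.25 to -0.16 for haem and iron and from -0.18 to -0.11 for KLF1-activated genes, and the last was -0.33 without doubly mutant replicate 1. Nfe2 lost its call without any of 4 of 15 arrays (adjusted p up to 0.0958) and Slc40a1 without any of 3 (up to 0.0739). Klf1 and Uros were each past the threshold in 9 of 28 alternatives, with adjusted p up to 0.276 and 0.295, and Trim58 in 14 of 28, with adjusted p up to 0.201.

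Macrophage markers were lower in doubly mutant than in wild-type arrays. Of 15 markers, 6 fell over all genes (Cd5l, Timd4, Marco, Adgre1, Fcgr1 and C1qa) and 14 adjusted over the list alone, with a median of -1.17. Timd4, a receptor for dying cells, fell 3.03-fold and Adgre1, which encodes a surface antigen of tissue macrophages, 2.61-fold. The list mean was 8.53 ± 0.79 (SD, n = 4) against 9.77 ± 0.18 (n = 4; exact permutation p = 0.0286, the smallest possible). Camera called the list (adjusted p = 2.85e-12), but not with an estimated correlation (adjusted p = 0.23). Cybb, a phagocyte oxidase subunit from the myeloid list, fell 2.56-fold; with the macrophage signal as a covariate its difference was 0.10 (adjusted p = 0.824; from 9.5e-05 over 28 alternatives, 12 past the threshold). C1qa passed in 13 of 27 alternatives (adjusted p up to 0.157). Fcgr1 and Adgre1 each lost their call without any of 5 of 15 arrays (adjusted p up to 0.088 and 0.0878), and Timd4 without wild-type replicate 3 (0.0601). Under that covariate, chosen after seeing the data, the count fell from 772 to 301.

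Other lists differed in doubly mutant arrays too. Among the stromal markers, the collagen genes Col1a1 and Col1a2 rose by 0.86 and 0.58, 2 of 10 over all genes and 3 adjusted over the list alone (camera adjusted p = 0.00285; adjusted p = 0.23 with an estimated correlation). The p53 targets Phlda3 and Ccng1 fell by 1.21 and 0.50, 2 of 13 over all genes and 5 adjusted over the list alone (adjusted p = 0.00334; adjusted p = 0.23 with an estimated correlation). Trib3, a stress-induced pseudokinase, rose by 0.70, and it was the only stress gene of 14 past the threshold (3 higher and 1 lower adjusted over the list alone; the list was not called). Among progenitor markers Spi1 rose and Mecom and Cd48 fell by 0.73 and 0.63, over all genes and adjusted over the list alone; the second Mecom cluster gave -0.14. Cd48 passed in 10 of 27 alternatives (adjusted p up to 0.809) and Ccng1 in 12 of 28 (up to 0.42). Mecom lost its call without any of 4 of 15 arrays (up to 0.082) and Col1a2 without any of 3 (up to 0.0856). Tlr6, a neighbour of Klf3, fell by 0.88. Under the macrophage covariate Col1a1 gave 0.61 (adjusted p = 0.225), Col1a2 0.55 (0.207), Tlr6 -0.32 (0.225), Trib3 0.88 (0.0585), Mecom -0.92 (0.0944), Cd48 -0.09 (0.809) and Ccng1 -0.31 (0.42), so that these 7 calls were lost. The published targets were called as before, 3 of 3, with adjusted p = 0.0164 with an estimated correlation, the only list call in this comparison that held. The test fry called 4 lists, the published targets, p53 targets (adjusted p = 0.00738), macrophage (adjusted p = 0.0195) and stromal markers (adjusted p = 0.0377). Cell cycle genes (0 of 28 past the threshold, median -0.14) and KLF3 corepressors (0 of 11, median 0.15) were called by camera at adjusted p = 9.84e-04 and 0.00718 (adjusted p = 0.501 and 0.489 with an estimated correlation). The corepressor list lost its call without doubly mutant replicate 4 (adjusted p = 0.0887), and its median was 0.09 without replicate 1 or 3 of that group. Without doubly mutant replicate 3 the medians were -0.08 for cell cycle and -0.09 for p53 targets, and the latter went from -0.17 to -0.11 without replicate 1. The count for all genes fell to 382 without wild-type replicate 3, and rose to 1389 without doubly mutant replicate 1 and to 2260 without both arrays that stood apart.

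Embryonic globins were the other planned readout of this comparison, since Kruppel-like factors act on the globin loci. Hbb-bh1 was 11.84 ± 0.67 in doubly mutant and 10.51 ± 0.66 in wild-type arrays (SD, n = 4 each), a difference of 1.33 ± 0.38 or 2.51-fold. Hba-x differed by 1.36 ± 0.38 (2.57-fold) and Hbb-y by 0.43 ± 0.18 (1.35-fold). None of these passed the threshold over all genes (adjusted p = 0.0698, 0.0683 and 0.202), whereas 3 of 3 were higher when adjusted over the list alone. In each gene 3 of 4 doubly mutant arrays lay above all wild-type arrays, and exact permutation gave p = 0.0571 (0.107 after Benjamini-Hochberg adjustment over 15 such tests). Camera called the list (adjusted p = 0.00241; adjusted p = 0.34 with an estimated correlation). Over 28 alternatives the adjusted p of Hbb-bh1 ran from 0.00159 to 0.323, with 7 past the threshold. Among the 7 were the planned replicate block and the fit without doubly mutant replicate 1 (1.66, adjusted p = 0.0115). Hba-x also passed with the replicate block. The permutation test does not use replicate numbers. The embryonic globin list mean was lowest on replicate 1 in wild-type (11.27), Klf8-trap (11.35) and doubly mutant arrays (12.51), but not in arrays labelled Klf3-null. Over all tested clusters, same-numbered doubly mutant and wild-type arrays did not go together (mean r = -0.03). No embryonic globin passed the threshold in either single mutant group against wild type: Hbb-bh1 gave 0.31 ± 0.38 in Klf8-trap arrays and -0.60 ± 0.41 in arrays labelled Klf3-null.

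**Figure D3:**
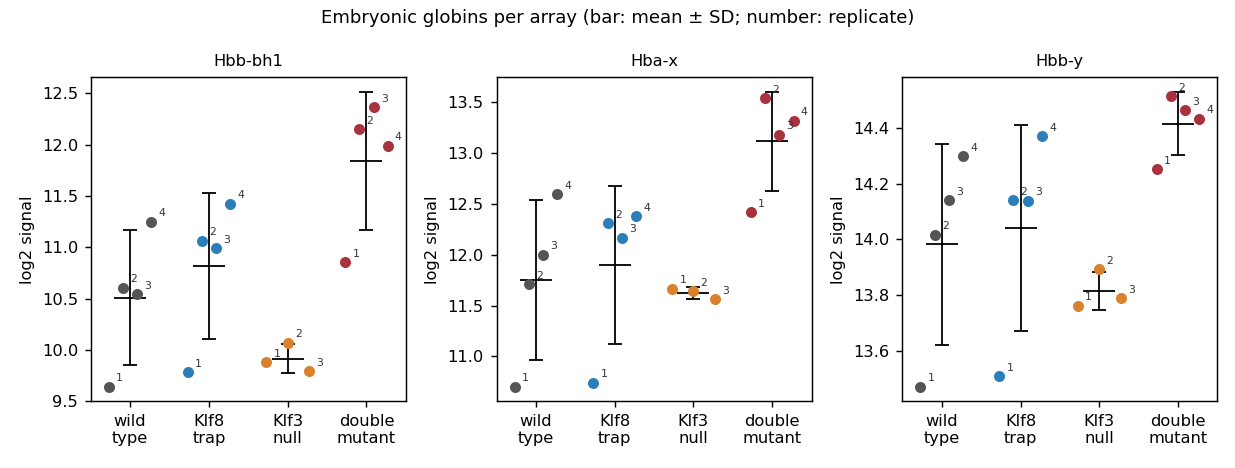
Log2 signal of the embryonic globin genes Hbb-bh1, Hba-x and Hbb-y on each array by genotype; points are arrays numbered by replicate, and bars give the mean ± SD. Doubly mutant arrays averaged 11.84 for Hbb-bh1 against 10.51 in wild type, with 1 doubly mutant array inside the wild-type range.

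Klf8-trap arrays gave no transcript cluster past the threshold against wild type. In limma 0 of 23410 passed, with 3135 at an unadjusted p under 0.05 and a smallest adjusted p of 0.107; the unmoderated linear model also gave 0, and array weights gave 4081. The genes with the smallest p were the microRNA gene Mir300, whose size is not given because its wild-type mean lay under the lower quartile of each wild-type array, Mir15a, Iyd (0.98 ± 0.18), the liver microRNA gene Mir122 (0.84 ± 0.15) and Bcl6 (0.65 ± 0.11) on the higher side. On the lower side they were Cdon (-0.81 ± 0.13), H2-M10.3, Fezf1, Rab25 and Olfr671, none past the threshold. Hepatocyte markers had a median difference of 0.65, and 14 of 14 had a positive sign; 0 passed over all genes and 13 were higher when adjusted over the list alone. The hepatocyte list mean was 12.41 ± 0.32 in Klf8-trap and 11.77 ± 0.17 in wild-type arrays (SD, n = 4 each; exact permutation p = 0.0571).

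Camera called 7 lists in this comparison and none with an estimated correlation (adjusted p = 0.775 for each of the 7). Hepatocyte (adjusted p = 2.89e-09) and megakaryocyte markers (adjusted p = 0.00143, median 0.57, 0 of 10 past the threshold over all genes or adjusted over the list alone) were higher. Macrophage markers (adjusted p = 0.0119, median -0.47), red cell membrane genes (7.11e-04, -0.16), haem and iron genes (0.00157, -0.15), KLF1-activated genes (0.00157, -0.17) and maturation genes (0.031, -0.16) were lower, with 0 members past the threshold over all genes or adjusted over the list alone. With the hepatocyte signal as a covariate, chosen after seeing the data, the medians of the last 4 turned to 0.0923, 0.0484, 0.0557 and 0.137. The megakaryocyte median was 0.96 without Klf8-trap replicate 1 and 0.32 without replicate 4. The macrophage list lost its call without Klf8-trap replicates 1 and 3 and wild-type replicate 3 (adjusted p = 0.11, 0.086 and 0.131), and the maturation list without Klf8-trap replicates 2 and 3 and wild-type replicates 2 and 3 (0.0571, 0.086, 0.0645 and 0.154). Klf8-trap replicate 1 decided the count. Without it 1683 clusters passed, 1079 higher and 604 lower, among them Mir300, the acute-phase gene Saa3 (1.74 ± 0.16), the carbonic anhydrase gene Car3 (1.52 ± 0.32) and Cdon (-0.96 ± 0.09). Leaving out any other single array gave 0.

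**Figure D4:**
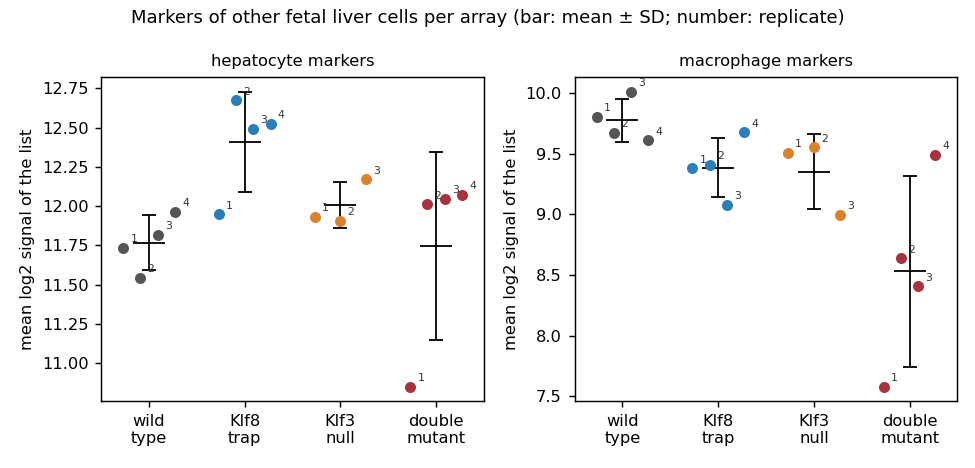
Mean log2 signal of 14 hepatocyte markers and of 15 macrophage markers on each array by genotype; points are arrays numbered by replicate, and bars give the mean ± SD. Hepatocyte markers averaged 12.41 in Klf8-trap and 11.77 in wild-type arrays, and macrophage markers averaged 8.53 in doubly mutant and 9.77 in wild-type arrays.

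The Klf8 trap on a Klf3-deficient background was read from doubly mutant arrays against those labelled Klf3-null. Here 11 clusters passed the threshold, 10 higher and 1 lower, the lower one being Klf8 itself. The integrin gene Itgb7 rose 2.77-fold (1.47 ± 0.16, adjusted p = 0.00346), Parm1 2.71-fold (1.44 ± 0.18), Gbp2b by 1.37 ± 0.16 on the log2 scale and Tnks1bp1 2.38-fold (1.25 ± 0.19). The helix-loop-helix factor gene Tcfl5, the ribosomal protein gene Rps3a1, the adhesion molecule gene Ncam1, the sulfotransferase gene Sult5a1 and the kinesin gene Kif21b rose by between 1.12 and 0.74 on the log2 scale, and Lipo3 rose from a level under the lower quartile of each array labelled Klf3-null. On the lower side Iigp1, Rnf7, Tmem251 and Mfsd4b1 had the smallest p after Klf8 and did not pass, with log2 differences from -0.51 to -0.47 for the last 3. Of the 11 calls, only that of Itgb7 held without each single array. That of Rps3a1 was lost on leaving out any of 9 of 15 arrays, Ncam1 of 7, Lipo3 of 6, Tnks1bp1, Tcfl5 and Klf8 of 4 each, Sult5a1 and Kif21b of 3 each, Parm1 of 2 and Gbp2b of 1, with adjusted p up to 0.255. With the macrophage signal as a covariate 10 of the 11 missed the threshold, all but Klf8, with adjusted p from 0.0503 for Itgb7 to 0.132 for Ncam1.

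Hbb-bh1 was higher by 1.92 ± 0.41 in this comparison (adjusted p = 0.124; 0.00202 to 0.413 over 28 alternatives, 6 of them past the threshold). Hba-x was higher by 1.49 ± 0.41 and Hbb-y by 0.60 ± 0.19, and 3 of 3 embryonic globins were higher when adjusted over the list alone. Camera called 10 lists and none with an estimated correlation. The macrophage list had a median of -0.85 (adjusted p = 1.77e-07, and 0.451 with an estimated correlation). Of its members 0 of 15 were past the threshold over all genes and 6 adjusted over the list alone. The median was -0.50 without doubly mutant replicate 1, and exact permutation of the list mean gave p = 0.114. Stromal markers had a median of 0.47 (adjusted p = 3.36e-05; adjusted p = 0.134 with an estimated correlation), with 0 of 10 and 5 adjusted over the list alone, among them Col1a1, Col3a1, Pdgfrb and Acta2. Embryonic globins gave adjusted p = 8.71e-05 (adjusted p = 0.284 with an estimated correlation). The erythroid lists other than transcription factors, and the apoptosis, interferon and stress lists, were called at adjusted p between 0.0219 and 0.0322 (adjusted p = 0.822 with an estimated correlation, and 0.451 for apoptosis). Without doubly mutant replicate 4 the KLF1-activated (median -0.07 in place of -0.17, adjusted p = 0.325), haem and iron (-0.08, 0.129), membrane (-0.04 in place of -0.14, 0.628) and maturation lists (-0.10 in place of -0.28, 0.548) lost their calls. These 4 calls were also lost without doubly mutant replicate 3 or Klf3-null replicate 1 or 2 (adjusted p from 0.0582 to 0.294), while without doubly mutant replicate 1 the medians were -0.25, -0.18, -0.25 and -0.44. The membrane median was -0.20 without doubly mutant replicate 2, and the haem and iron median went from -0.11 to -0.07 without Klf3-null replicate 2 and to -0.08 without doubly mutant replicate 3. Without Klf3-null replicate 1 the calls of interferon (-0.09 in place of -0.28, adjusted p = 0.768), apoptosis (-0.07 in place of -0.13, 0.0958) and stress genes (0.06 in place of 0.11, 0.0958) were lost. Interferon (0.0582) and apoptosis (0.0789) also lost theirs without doubly mutant replicate 3, and stress genes without replicates 2 (0.04, 0.427) and 4 (0.146) of that group; the stress median was 0.18 without replicate 3. The count of 11 rested on few arrays: it was 1 without Klf3-null replicate 3 and 484 without doubly mutant replicate 4, and 0 with only the groups compared in the fit.

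Loss of Klf3 in the presence of the trap was read from doubly mutant against Klf8-trap arrays, which share no array with the comparison of Klf3-null and wild type. Pqlc3 (17.8-fold), Rragd (15.1-fold), C1qtnf12 (3.32 ± 0.16 on the log2 scale), Kdelr3 (3.20 ± 0.17), Lgals3 (8.64-fold) and Supt3 (8.32-fold) rose most, followed by Cttnbp2nl, Dkkl1, Prune2 and Cyp4f39 at log2 differences from 2.65 to 2.49. Spi1 rose by 2.49 ± 0.18, and Klf8 and Klf3 were higher by 1.90 and 1.10. In all 785 clusters passed, 347 higher and 438 lower. With the replicate number as a block of these 2 groups alone, a fit chosen after seeing the data, 2178 passed, 702 higher and 1476 lower, among them all 785. The largest falls were in Car3 (5.37-fold), the protease inhibitor gene Pzp (3.97-fold), the coagulation factor gene F13b (3.97-fold), Cd5l (3.72-fold), Grap2 (3.62-fold), Ces1d, Ugt2b36 and the complement gene C8b. Cd209f and Cyp3a16 fell too, to means under the lower quartile of each doubly mutant array, so the size of their falls is not given. The call of Ugt2b36 was lost without Klf8-trap replicate 2 or 4 (adjusted p = 0.0543 and 0.0549) and with the hepatocyte (-1.15, 0.0934) or macrophage signal (0.085) as a covariate. The latter also ended the calls of C8b (-1.33, 0.0653) and Cyp3a16 (0.124).

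Of 137 clusters called in Klf3-null against wild-type arrays, 135 had the same sign in this comparison and 115 were also called with that sign, 105 higher against 1.81 expected of independent lists and 10 lower against 0.281. Both comparisons share 1 estimate of the spread of each cluster, which can raise the number called in both. The correlation across those 137 clusters was 0.91. Across all 23410 clusters it was 0.163 (Spearman -0.111), within the range of -0.729 to 0.55 from 100 simulated draws without effects; clusters are not independent replicates. The published targets were called as before (3 of 3, also adjusted over the list alone; adjusted p = 0.0189 with an estimated correlation, and 0.0574 with the replicate block of both groups).

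**Figure D5:**
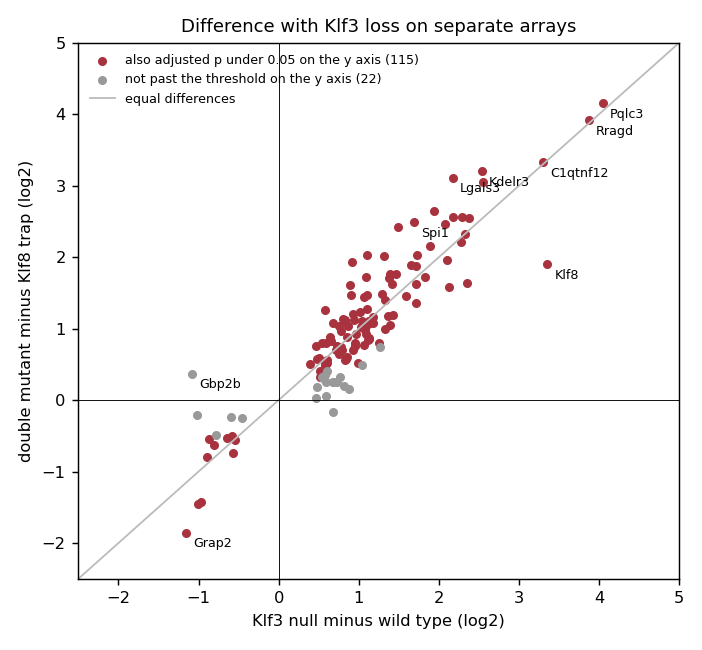
Log2 difference of doubly mutant minus Klf8-trap arrays against that of Klf3-null minus wild-type arrays, for the 137 transcript clusters past the threshold in the latter; red points passed in both and the grey line marks equal differences. Of the 137, 135 had the same sign on both axes and 115 were called in both, with a correlation of 0.91.

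Hepatocyte markers were lower in doubly mutant than in Klf8-trap arrays by a median of 0.64 (-0.64). Of 14, the plasma protein genes Ahsg (-1.10 ± 0.26) and Apoh (-1.35 ± 0.29) fell over all genes and 7 were lower adjusted over the list alone (camera adjusted p = 1.8e-06; adjusted p = 0.528 with an estimated correlation). Without doubly mutant replicate 1, whose hepatocyte list mean was 10.85 against 12.01 to 12.07 in its group, the median was -0.31 (camera adjusted p = 4.57e-04), Ahsg gave -0.78 (adjusted p = 0.0397) and Apoh -1.05 (adjusted p = 0.0271). Both calls were lost without Klf8-trap replicate 2 (adjusted p = 0.114 and 0.0669) or 4 (0.107 and 0.0607), and that of Ahsg without replicate 3 (0.0837). With the macrophage signal as a covariate Ahsg gave -0.70 (0.402) and Apoh -1.03 (0.239). Among macrophage markers Cd5l, Marco and the adhesion receptor gene Vcam1 fell, 3 of 15 over all genes and 7 adjusted over the list alone (adjusted p = 4.7e-07; adjusted p = 0.488 with an estimated correlation); their median was -0.79, and -0.44 without doubly mutant replicate 1. The calls of Marco (adjusted p up to 0.0571) and Vcam1 (up to 0.0822) were lost without Klf8-trap replicate 2 or 4, and that of Vcam1 also without replicate 3. With the hepatocyte signal as a covariate Vcam1 gave -0.48 (0.102) and Marco -0.89 (0.0938). Exact permutation of the list means in this comparison gave p = 0.114 for hepatocyte and p = 0.114 for macrophage markers.

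Other listed genes passed in the same comparison. Ldb1, Trib3, Fos, Col1a1, Col1a2, the colony-stimulating factor receptor gene Csf3r and the ferrireductase gene Steap3 rose by between 0.43 and 0.88, and Phlda3, Ypel4, Mecom, Tlr6, Ccng1 and Aqp1 fell, with log2 differences from -1.15 to -0.49. Aqp1 passed in 7 of 29 alternatives (adjusted p up to 0.301) and Steap3 in 11 of 29 (up to 0.297). Fos lost its call without any of 9 of 15 arrays (adjusted p up to 0.11), Col1a2 of 4 (0.0753), Ypel4 of 3 (0.0635) and Trib3 of 2 (0.0696). Ccng1 (0.0505) and Tlr6 (0.0586) lost theirs without Klf8-trap replicate 4. Under the macrophage covariate Col1a1 gave 0.71 (adjusted p = 0.136), Col1a2 0.55 (0.197), Tlr6 -0.32 (0.221), Ccng1 -0.49 (0.202), Trib3 0.78 (0.052) and Fos 0.76 (0.0589), and under the hepatocyte covariate Mecom gave -0.73 (0.0586), Tlr6 -0.53 (0.0914) and Ccng1 -0.54 (0.0623).

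Embryonic globins and further lists were examined in this comparison too. Hba-x was higher by 1.21 ± 0.38 (adjusted p = 0.0974) and Hbb-bh1 by 1.02 ± 0.38 (adjusted p = 0.153), and camera called the embryonic globin list (adjusted p = 0.02; adjusted p = 0.488 with an estimated correlation), with 3 of 3 higher adjusted over the list alone. The list call was lost without Klf8-trap replicate 1 (median 0.68 in place of 1.02, adjusted p = 0.12) and without doubly mutant replicate 2 (0.0573). With the replicate block of these 2 groups alone both genes passed, Hba-x with adjusted p = 0.0187 and Hbb-bh1 with adjusted p = 0.0214 (0.0122 and 0.0186 with the block planned over all arrays). Camera also called the Kruppel-like factor family (0.0237, median 0.17), granulocyte (0.0237, 0.20), stromal (0.027, 0.19), megakaryocyte (0.0167, -0.58), apoptosis (0.00367, -0.15), cell cycle (0.0406, -0.09) and interferon lists (0.041, -0.27), given as adjusted p and median. Of these, none held with an estimated correlation (adjusted p from 0.312 to 0.729). With the block of both groups camera no longer called the cell cycle (adjusted p = 0.0649) and interferon lists (0.0761) and called the maturation list (0.0359, median -0.24; adjusted p = 0.652 with an estimated correlation). The test fry then called the hepatocyte (0.00583), macrophage (0.0316), megakaryocyte (0.0408), stromal (0.0489) and embryonic globin lists (0.0489), none of which it called without the block (adjusted p from 0.117 to 0.321). Leaving out single arrays ended 6 of these 7 camera calls. Without Klf8-trap replicate 4 the megakaryocyte call was lost (median -0.35, adjusted p = 0.0963), as it was without doubly mutant replicate 1 (0.0536), and without Klf8-trap replicate 1 its median was -0.93. The granulocyte call was lost without doubly mutant replicate 1 (0.06, adjusted p = 0.2), doubly mutant replicate 2 (0.0541) and Klf8-trap replicate 1 (0.0613), with a median of 0.31 without doubly mutant replicate 4. The Kruppel-like factor call was lost without Klf8-trap replicate 1 (0.0513) and doubly mutant replicate 2 (0.0541), and its median was 0.06 without Klf8-trap replicate 4. The stromal call was lost without Klf8-trap replicate 1 (0.114) and doubly mutant replicate 2 (0.0737). Cell cycle genes lost theirs for 4 of 15 arrays, up to adjusted p = 0.558 without doubly mutant replicate 3 (median -0.02), with -0.05 without replicate 2 and -0.13 and -0.14 without replicates 1 and 4 of that group. Interferon genes lost theirs for 6 arrays, up to adjusted p = 0.227 without Klf8-trap replicate 2 (-0.16). The apoptosis list stayed called without each array, with a median of -0.07 without doubly mutant replicate 1. The count of 785 ranged from 393 without Klf8-trap replicate 4 to 1777 without doubly mutant replicate 4.

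The interaction asks whether the effect of Klf3 loss differed with the trap. Only Itgb7 passed the threshold, with an interaction of 1.68 ± 0.22 on the log2 scale (adjusted p = 0.0311) among 23410 clusters, and 3378 had an unadjusted p under 0.05. Its signal was 8.09 ± 0.30 in doubly mutant arrays, 6.62 ± 0.14 in arrays labelled Klf3-null, 5.92 ± 0.17 in Klf8-trap and 6.14 ± 0.25 in wild-type arrays. Among genes that did not pass, Gbp2b (1.44), the small nucleolar RNA gene Snord15b (1.40), Kif21b (0.87) and Acap1 (0.84) had the smallest p on the positive side. Fabp2 (-2.13), Mir15a (2.82-fold lower), Iyd (-1.48), Cyp2d10 (-1.10) and Lgals2 (-0.92) had the smallest on the negative side. The interaction was -1.45 ± 0.30 for Klf8 (adjusted p = 0.113) and 1.62 ± 0.55 for Hbb-bh1 (adjusted p = 0.223). Itgb7 passed in 13 of 26 alternatives (adjusted p from 0.00196 to 0.214), and leaving out 1 array ended its call for 9 of 15 arrays. The count was 718 without Klf8-trap replicate 1, and 746 without it and doubly mutant replicate 1.

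Camera called 5 lists in the interaction, none with an estimated correlation. Hepatocyte markers (median -0.99, adjusted p = 4.71e-07) had 0 of 14 past the threshold over all genes and 8 lower adjusted over the list alone. Embryonic globins (1.34, 0.0242) had 0 of 3 and 2, stromal markers (0.42, 0.0242) 0 of 10 and 1, and interferon (-0.37, 0.0242) and megakaryocyte genes (-0.73, 0.0441) 0 in both counts. The adjusted p with an estimated correlation was 0.622 for the first 3 of these and 0.831 for the last 2. Only the hepatocyte call held without each single array. That of embryonic globins was lost without Klf8-trap replicate 1 (median 0.96, adjusted p = 0.114) and doubly mutant replicate 2 (0.051), and that of stromal markers without these arrays (0.088 and 0.051) and Klf3-null replicate 2 (0.0579). Interferon genes lost theirs for 6 of 15 arrays, up to adjusted p = 0.278 without Klf3-null replicate 1 (-0.24), and megakaryocyte genes for 10, up to 0.174 without Klf8-trap replicate 4; without Klf8-trap replicate 1 the megakaryocyte median was -1.11.

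The calls of both Klf3-deficient groups against wild type overlapped. Of 122 clusters higher in arrays labelled Klf3-null, 116 were also higher in doubly mutant arrays, against 1.86 expected of independent lists, and of 15 lower, 13 were also lower, against 0.267. None was called in opposite directions. Both comparisons use the same wild-type arrays, which alone raises such an overlap. The log2 differences correlated at 0.609 across clusters with a covariance of 0.0337, and simulated groups without effects gave a mean correlation of 0.401 (range -0.664 to 0.87, which holds the observed value) and a mean covariance of 0.00943. With the wild-type arrays split into 2 and 2, the correlation was 0.366 to 0.565. For the Klf8 trap and the doubly mutant group against wild type, the correlation was 0.407 against a simulated mean of 0.48 (range -0.383 to 0.805). The covariance was 0.0226 against 0.0105, and the split arrays gave 0.184 to 0.383. For the Klf8 trap and the Klf3-null group the correlation was 0.55 against a simulated mean of 0.439 (range -0.297 to 0.899), the covariance 0.0247 against 0.0104, and the split arrays gave 0.266 to 0.43.

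Lists with no call from camera in any comparison were the haematopoietic progenitor, endothelial, lymphoid and mast cell lists, the Y-linked and X-inactivation genes and the genes next to Klf3. In doubly mutant against wild-type arrays their medians were -0.06, -0.11, -0.03, -1.76 and 0.05, with camera adjusted p of 0.838, 0.865, 0.567, 0.511 and 0.687. For the progenitor list the mean (0.09) and camera's direction were positive, and for the genes next to Klf3 the mean was -0.01. Granulocyte markers gave a median of 0.04 there (adjusted p = 0.35) and interferon genes -0.15 (adjusted p = 0.333). Hepatocyte and megakaryocyte markers gave -0.01 and -0.05 (adjusted p = 0.838 for both, with camera's direction positive). Aquaporins gave 0.21 (adjusted p = 0.385).

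The 5 relations between list means within groups were examined over the 15 arrays. Red cell membrane genes went down where hepatocyte markers went up (r = -0.808, Spearman rho = -0.729, permutation p = 0.00117, 0.00585 after Benjamini-Hochberg adjustment; r = -0.606 without the 2 farthest arrays). Embryonic globins went up with hepatocyte markers (r = 0.695, rho = 0.675, permutation p = 0.0191, adjusted 0.0319; r = 0.413 without the 2 farthest arrays). Aquaporins went down with embryonic globins (r = -0.843, rho = -0.754, permutation p = 0.00336, adjusted 0.0084; r = -0.659 without the 2 farthest arrays). For macrophage (r = 0.581, permutation p = 0.313) and megakaryocyte markers (r = 0.577, permutation p = 0.169) the relation to hepatocyte markers did not pass the threshold (r = 0.192 and 0.19 without the 2 farthest arrays).

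Genes near Klf3 were counted because a segment around a mutated allele can carry variants of another strain. Of 84 clusters within 10 Mb of Klf3, 2 passed in Klf3-null against wild-type arrays (2.38% against 0.588% elsewhere, Fisher p = 0.0893). In doubly mutant arrays 6 passed against wild type (7.14% against 3.38%, Fisher p = 0.0658) and 6 against Klf8-trap arrays (7.14% against 3.37%, Fisher p = 0.0651). Within 5 Mb, 1, 3 and 2 of 47 clusters passed in these 3 comparisons (Fisher p = 0.245, 0.213 and 0.673).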

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

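In 303 groups of 4 values, from 78 genes and 23 list means, a value was set apart by a Dixon ratio in 15 groups, where 15.2 are expected by chance at about 1 in 20 groups. Of the 15, 8 belonged to Klf8-trap replicate 1. They were Hba-x (ratio 0.870; 10.74 against a mean of 12.29 in the other 3 arrays), Asb2 (0.864), Nfe2 (0.878) and the list means of KLF3 corepressors (0.883), KLF1-activated genes (0.878), maturation genes (0.915), aquaporins (0.896) and endothelial markers (0.919). Doubly mutant replicate 1 had a hepatocyte list mean of 10.85 against 12.04 in the rest of its group (ratio 0.950). The others were Tmem26 (0.974) and the interferon list mean (0.912) in wild-type replicate 3, Rps3a1 in wild-type replicate 1 (0.945), Csf3r in wild-type replicate 2 (0.916), Car3 in doubly mutant replicate 2 (0.871) and the interferon list mean in doubly mutant replicate 3 (0.929).

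The interaction held 5 lists called by camera with the preset correlation, embryonic globins (median 1.34), interferon (-0.37), hepatocyte (-0.99), megakaryocyte (-0.73) and stromal genes (0.42), and 1 gene, Itgb7 (1.68). With an estimated correlation none of the 5 was called (adjusted p = 0.622 for embryonic globins, hepatocyte and stromal genes, and adjusted p = 0.831 for interferon and megakaryocyte genes). Only the hepatocyte call held without each single array, and that of Itgb7 was lost for 9 of 15 arrays. With all 35556 clusters in the fit, in place of the 23410 with a symbol, 636 passed the threshold in doubly mutant against wild-type arrays. Of these 636, 118 had no gene symbol, 43 of them higher, and these 118 were not analysed here.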

How the results depend on the processing

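Outside doubly mutant against Klf8-trap arrays, not every same-numbered pair correlated above 0.1, so these numbers were not taken as pairs. For doubly mutant against Klf3-null arrays the same-number matching also had the highest mean of 24 (0.103), with 3 pairs from 0.0707 to 0.158. Over all 21 pairs of same-numbered arrays the correlation ran from -0.28 to 0.53, with 8 above 0.1, and only 6 arrays lay closest to their own number. For that comparison the replicate block of both groups alone gave 2178 calls in place of 785, and 10 lists. It changed the calls of Hba-x, Hbb-bh1 and the lists named with it, and no other call of a named gene or list. The block planned over all arrays gave 944 calls and 12 lists there; Aqp1 then missed the threshold (-0.49, adjusted p = 0.0585), camera called the maturation list (adjusted p = 0.0335; adjusted p = 0.667 with an estimated correlation), and fry called the embryonic globin (0.0197) and stromal lists (0.0456). Between 3 and 4 arrays per group, single arrays move most counts. Of the genes named as past the threshold, 13 of 23 kept their call under every setting in Klf3-null against wild type, 20 of 44 in doubly mutant against wild type, 0 of 11 against Klf3-null and 20 of 40 against Klf8-trap arrays, and 0 of 1 in the interaction.

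Of the named calls, the macrophage signal as a covariate ended 2 in Klf3-null against wild type, 17 in doubly mutant against wild type, 10 against Klf3-null and 13 against Klf8-trap arrays. The hepatocyte signal ended 8 against Klf8-trap arrays and 1 in the interaction. With only the groups compared in the fit, 18, 11 and 18 calls were lost in the 3 comparisons of doubly mutant arrays, in the order above, and the unmoderated model ended 15, 11 and 13, as well as 5 in Klf3-null against wild type. Male embryos alone lost 7 in Klf3-null against wild type and 10, 11 and 9 in those 3 comparisons.

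For Klf8-trap against wild-type arrays the count of 0 became 4081 with array weights, 142 with the macrophage signal as a covariate, 318 among male embryos and 2917 without both arrays that stand apart; leaving out 1 array gave 0 (without wild-type replicate 1) to 1683 (without Klf8-trap replicate 1). For Klf3-null against wild type, 137 became 78 in the unmoderated linear model, 481 with only the groups compared in the fit, 597 with array weights, 218 with the hepatocyte signal, 40 among male embryos and 296 without both arrays that stand apart; leaving out 1 array gave 61 (Klf3-null replicate 1) to 180 (doubly mutant replicate 4). For doubly mutant against wild type, 772 became 295 with only the groups compared, 475 at 1.5-fold or more, 1400 at a threshold of 0.1, 1921 with the hepatocyte and 301 with the macrophage signal, and 2260 without both arrays that stand apart. Leaving out 1 array gave 382 (wild-type replicate 3) to 1389 (doubly mutant replicate 1).

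For doubly mutant against Klf3-null arrays, 11 became 5 without dim clusters, 6 over all clusters, 0 in the unmoderated model, 0 with only the groups compared, 55 with array weights, 17 at a threshold of 0.1, 478 with the hepatocyte and 1 with the macrophage signal, 0 among male embryos and 162 without both arrays that stand apart. Leaving out 1 array gave 1 (Klf3-null replicate 3) to 484 (doubly mutant replicate 4). Against Klf8-trap arrays, 785 became 476 in the unmoderated model, 188 with only the groups compared, 1280 with array weights, 452 at 1.5-fold, 1585 at 0.1, 1210 with the hepatocyte and 235 with the macrophage signal, 1610 among male embryos and 1245 without both arrays that stand apart. Leaving out 1 array gave 393 (Klf8-trap replicate 4) to 1777 (doubly mutant replicate 4). The interaction count of 1 became 13 with the replicate block, 0 with the Y-linked signal, 0 without dim clusters, 0 over all clusters, 0 in the unmoderated model, 1183 with array weights, 21 at 0.1, 4 with the hepatocyte and 2 with the macrophage signal, 411 among male embryos and 746 without both arrays that stand apart. Leaving out 1 array gave 0 (wild-type replicate 2) to 718 (Klf8-trap replicate 1).

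The Klf3 difference of Klf3-null against wild type was 0.89 among male embryos. In doubly mutant against wild type Hba-x gave 1.36 with the replicate block, 1.53 with array weights, 1.39 with the hepatocyte signal and 1.59 without both arrays that stand apart, all past the threshold, and 1.01 to 1.64 over single arrays left out (wild-type replicates 1 and 4). Hbb-bh1 gave 1.33, 1.46, 1.36 and 1.66 under the same 4 settings, and 1.04 to 1.66 (wild-type replicate 1, doubly mutant replicate 1). Cybb gave 0.10 with the macrophage signal. Against Klf3-null arrays Hbb-bh1 gave 1.76 with the replicate block, 1.97 with array weights, 2.25 with the hepatocyte signal and 2.25 without both arrays that stand apart, and 1.75 to 2.25 over single arrays left out (doubly mutant replicates 3 and 1). Hba-x gave 1.79 with the hepatocyte signal and 1.72 without both arrays that stand apart. Klf8 gave -1.42 in the unmoderated model and with only the groups compared, -1.40 after quantile normalization and -0.72 among male embryos, none past the threshold, and -1.68 to -1.28 (doubly mutant replicates 1 and 3).

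Against Klf8-trap arrays Hba-x gave 1.21 with the replicate block and 1.98 with the hepatocyte signal, and Hbb-bh1 1.02 and 1.87, with 0.68 to 1.35 over single arrays left out (Klf8-trap replicate 1, doubly mutant replicate 1). In the interaction Hbb-bh1 gave 1.60 without both arrays that stand apart, and Klf8 gave -1.45 with array weights, -2.09 with the hepatocyte signal, -1.67 without both arrays that stand apart, and -1.70 to -1.30 over single arrays left out (doubly mutant replicates 1 and 3). With the hepatocyte signal the medians of Klf8-trap against wild type turned to 0.0557 for KLF1-activated, 0.0484 for haem and iron, 0.0923 for membrane and 0.137 for maturation genes, that of granulocyte markers against Klf8-trap arrays to -0.0555, and that of megakaryocyte markers in the interaction to -0.0445.

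Lists called numbered 0 with an estimated correlation and 0 by fry for Klf8-trap against wild type. For Klf3-null against wild type they numbered 8 with the replicate block, 8 without dim clusters, 6 with the hepatocyte signal, 5 without both arrays that stand apart and 1 with an estimated correlation, and 2 to 10 over single arrays left out (wild-type replicate 3, Klf3-null replicate 2). Doubly mutant against wild type had 1 with an estimated correlation and 4 by fry. Against Klf3-null arrays there were 6 with the replicate block, 5 without dim clusters, 0 with an estimated correlation and 1 by fry, and 3 to 15 (Klf3-null replicate 1, doubly mutant replicate 1). Against Klf8-trap arrays there were 1 with an estimated correlation and 3 by fry, and 5 to 16 (Klf8-trap replicate 1, doubly mutant replicate 1). The interaction had 1 with the Y-linked signal, 14 with the hepatocyte signal, 3 without both arrays that stand apart, 0 with an estimated correlation and 0 by fry, and 1 to 7 (doubly mutant replicate 2, Klf3-null replicate 3).

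Calls shared by both Klf3-deficient groups against wild type numbered 73 in the unmoderated model, 315 with array weights, 38 among male embryos and 249 without both arrays that stand apart, and 57 to 156 over single arrays left out (Klf3-null replicate 1, doubly mutant replicate 4). The correlation of the Klf3 effect without and with the trap was 0.104 with the replicate block, 0.290 without dim clusters, 0.0799 over all clusters, 0.0808 with array weights, 0.256 with the hepatocyte and 0.378 with the macrophage signal and -0.0974 among male embryos, and 0.0405 to 0.258 over single arrays left out (Klf8-trap replicate 1, doubly mutant replicate 1). That of the trap effect with and without Klf3 was -0.142 with the replicate block, 0.0292 over all clusters, -0.158 with the hepatocyte and 0.369 with the macrophage signal, -0.346 among male embryos and 0.193 without both arrays that stand apart, and -0.154 to 0.172 (doubly mutant replicates 3 and 1).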

Other observations

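All tests in this part were chosen after the result was seen, except the counts over all regroupings and the fits with 1 array left out and no covariate, which were fixed before, though the use of those fits to weigh an explanation was not.

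Arrays were regrouped across labels to see how often a count as large arises. The count of Klf3-null against wild-type arrays, 137, was reached by 1 of 35 splits, the labelled one, and the highest other split gave 1. For doubly mutant against wild type, 772 was reached by 1 of 35, with 11 as the highest other. The count of 11 for doubly mutant against Klf3-null arrays was reached by 4 of 35 splits, with 837 the highest, and that of 785 against Klf8-trap arrays by 2 of 35, with 2448 the highest. That split parts 2 of the 4 replicate pairs of these groups, and of the 8 splits that part all 4 only the labelled one gave a call. These pairs were read from the same values, and 1 of 8 is the smallest share possible. The 8 splits therefore cannot decide whether the labels account for the count of 785. For the Klf8 trap against wild type all 35 splits reached 0, and the highest gave 733. For the interaction 10 of 100 regroupings reached 1, and the highest gave 1573.

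Doubly mutant arrays differed from wild type at more clusters than Klf3-null arrays did, 772 against 137. Unequal group size does not account for it, since with 3 doubly mutant arrays the lowest count was 496. Among male arrays alone, 2 doubly mutant and 4 wild-type arrays gave 744, so the doubly mutant count does not need a difference in sex. Only 1 male Klf3-null array was left, so that both counts could not be compared within males. Lower macrophage RNA could not be told apart: with the macrophage signal as a covariate and 3 doubly mutant arrays the count was 12 to 376, against 124 to 198 for Klf3-null arrays. Over 643 clusters called in doubly mutant arrays alone, the median signed difference went from 0.63 to 0.54 with that covariate. The median standard error went from 0.13 to 0.18, so that 122 calls were left. A call against wild type in doubly mutant arrays alone does not show a difference between both mutant groups. The direct comparison of doubly mutant and Klf3-null arrays called only 11 clusters. Of these, 7 were also called as higher against wild type, and 1 was called in opposite directions.

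Klf8-trap replicate 1 decided the count against wild type, which was 1683 without it. A lower share of erythroid cells in the other 3 arrays could not be told apart. Their macrophage median against wild type was -0.46 while the hepatocyte median was 0.79. However, the macrophage list mean of replicate 1 (9.38) lay within those of the other 3 arrays (9.08 to 9.68). Replicate 1 was lower in endothelial (7.68 against 8.59 to 8.67) and megakaryocyte markers (9.44 against 10.4 to 10.94). It was higher in KLF1-activated genes (11.79 against 11.55 to 11.58). Lymphoid and mast cell markers went the other way, at 5.34 on replicate 1 and 5.04 to 5.20 in the other 3 arrays. More hepatocyte RNA in them could not be told apart: with the hepatocyte signal as a covariate there were 12 calls, 9 of them among the 1683, but the median signed difference of the 1683 only went from 0.51 to 0.33, with a median standard error of 0.12 before and 0.14 after. A Klf3-null or doubly mutant array under this label does not account for it, since the published KLF3 targets averaged 7.12 there against 9.23 or more on the Klf3-deficient arrays. A wild-type array under this label could not be told apart, because Klf8 differed by only 0.0249 between Klf8-trap and wild-type arrays.

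Embryonic globins were higher in doubly mutant arrays without passing the threshold over all genes. Against Klf8-trap arrays the hepatocyte list mean was lower in doubly mutant arrays (-0.67), while embryonic globins went up with it within groups (r = 0.695). A difference that goes with hepatocyte markers would thus lower the globins in that comparison. The covariate could only raise their differences there, to 1.87 from 1.02 for Hbb-bh1 and to 1.98 from 1.21 for Hba-x. Against wild type the covariate left Hbb-bh1 at 1.36 (adjusted p = 0.00389), but this fit cannot decide the question. The hepatocyte list mean differed from wild type by only -0.02, so that the covariate could hardly change the estimate. Without doubly mutant replicate 1 the covariate took Hbb-bh1 from 1.66 ± 0.35 (SE, adjusted p = 0.0115) to 1.19 ± 0.31 (0.0673). It took Hba-x from 1.59 ± 0.39 (0.0274) to 1.01 ± 0.33 (0.146) and Hbb-y from 0.49 to 0.24. How much of the difference from wild type goes with hepatocyte markers therefore could not be told, for any of these genes. Embryo age and sort purity were not measured. Carry-over of primitive erythroid cells could not be told apart by the aquaporins, whose within-group correlation with embryonic globins was -0.84 and whose median difference was 0.21.

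A hypothesis is that the Klf8 trap adds to the changes that follow loss of Klf3. Over 557 genes called by the mean Klf3 effect, the median interaction signed by that effect was 0.15, and 69.3% were positive. Of 100 regroupings 4 gave a value as large, with 0.23 the highest other, and leaving out 1 array gave 0.09 to 0.24. The 557 genes and their signs were taken from these same arrays and were kept fixed in the regroupings. A larger spread of doubly mutant arrays could therefore raise the value without an effect of the trap. Array weights, lower for arrays with more spread, were 0.43 to 1 in that group and 1.08 to 1.70 in Klf3-null arrays. The regroupings therefore cannot decide the hypothesis. The median size of the effect was 0.48 without and 0.63 with the trap. The median signed interaction was 0.10 over the genes that rose and 0.19 over those that fell. No cell marker signal was used as a covariate in this test. Lower macrophage RNA in doubly mutant arrays therefore could not be told apart from an effect of the trap. The hypothesis may be tested in further litters with the trap and Klf3 alleles, by whether the same genes change more in doubly mutant embryos.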
